A study of Homo sapiens with 18 samples.

How the data were processed

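Newly made RNA labelled with 4-thiouridine was measured in HEK293T cells carrying a degron tag on INTS8, with and without auxin, in 3 libraries each. Per the labels' protocols, total RNA was cleared of DNA and fragmented, labelled fragments were biotinylated and pulled down, and libraries were made with a stranded dUTP kit. STAR 2.7.3a, DESeq and the builds hg38 and dm6 are named in the submitters' processing notes, without their roles. The read counter, the annotation version, the strand setting of the counting and any use of a fly spike-in are not given in the sources used here, and the table lists no fly genes.

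The deposited table has 1 row per gene, with exonic values for 14538 genes, of which 12824 are protein-coding, 1384 lncRNA and 110 snRNA genes. Per the file headers, the library columns are normalized counts, a signal that is never negative, and the table also holds their mean. The authors' comparison columns hold a fold (ratio) of auxin plus over minus, its log2 with an SE, a test score and p-values, per the file headers, together with a transcript length and an interval per gene (other numbers) that the authors list. All 6 library columns were matched to samples by name. Every value was a whole multiple of 1 step per library (100% of values within a tolerance of 1e-06), so the table keeps read counts divided by a size factor, and the reads were recovered as value times size factor. The size factors, 0.898 to 1.11, equal to 6 decimals the median-of-ratios factors computed here from the 13702 genes with reads in all libraries, so fold changes are relative to the median gene and show no change shared by all genes. Recovered totals were 5137155 to 6066384 reads per library, 106 genes had none, and the 10 most abundant genes took between 1.53% and 1.81%. Numbers of reads limit precision mostly for genes under the mean of 50 used below. Intervals that the authors list fitted hg38: of 13301 symbols found in a RefSeq table of that build, 99.9% overlapped its interval. In 19 rows the listed start lay after the end, and these were left out of span analyses.

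The test fixed before the data were examined was edgeR's quasi-likelihood test for raw counts, with limma as the alternative for normalized values. As the table holds normalized values, the main test was limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(value + 1), which understates the change of low genes, after edgeR's filterByExpr on recovered reads left 12726 genes. P-values are two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. edgeR 4.0.16, DESeq2 1.42.0 and limma-voom were run on the recovered reads as alternatives, of which edgeR with TMM called 1029 genes higher and 472 lower. The authors' deposited table has an adjusted p for 13592 genes and none for 946, and calls 892 higher and 390 lower. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Exact permutation of 3 against 3 libraries cannot give a p under 0.1, so single genes were not tested that way. Replicates of a group correlated with r from 0.986 to 0.991 over genes, and pairs across groups with r from 0.966 to 0.975, and no replicates agreed within sampling noise.

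In all, 30 gene lists were fixed before the data were examined, together with most alternatives and the rule for named genes. Of these, 27 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 27, with fry beside it. At the preset correlation 11 lists passed, and 0 with an estimated correlation. The latter setting also uses only the residual degrees of freedom of the 6 libraries, so its loss of calls is not due to correlation alone. For members, counts are given over all genes and, for lists that passed or where they differ, adjusted over the list alone. The rule named the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 50 and groups apart, up to 4 called members per list by adjusted p or else the 1 with the smallest p, INTS8, ATF4, ATF3, DDIT3, FOS, JUN and EGR1 in any case, and genes needed for counts of 5 or fewer. Further list members named as examples were chosen after their values were seen. A gene that the rule names is not reported here. Classes are those of the table, and spans were binned at 2, 10, 50 and 200 kb.

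Alternatives fixed beforehand covered normalization (library totals, DESeq2 size factors in edgeR), the test, the filter, the threshold, the pseudocount (0.1 and 5), each library left out in turn, and the replicate number as a block. Chosen after seeing the data, once limma was the main test, were limma after TMM scaling, edgeR on the recovered reads with TMM, library totals or a block, the authors' deposited calls, leaving out both libraries that stood apart from their replicates, and most settings for span. On simulated data with the real means and library sizes, limma recovered 71.6% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes. Each rate rests on 66 or 67 changed genes among 12726, and 9 unchanged genes were called. The simulation held no libraries that stand apart from their replicates, so these rates may not hold for the real libraries. Random lists were 10000 draws matched on mean level in bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some annotated gene overlaps could mix reads, and genes with near-identical copies are marked as uncertain where named.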

Results

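Newly made RNA was measured by transient transcriptome sequencing (TT-seq), in which cells take up 4-thiouridine for a short pulse and the labelled RNA is fragmented, captured through biotin and sequenced. The cells were HEK293T, a human embryonic kidney line that grows fast and is widely used for genetic engineering. In the INTS8-AID derivative, INTS8, a subunit of the Integrator complex that links its RNA endonuclease to protein phosphatase 2A, carries an auxin-inducible degron, so that auxin leads to breakdown of the tagged protein. The series holds 18 samples, and the 6 INTS8-AID libraries were compared here, 3 from cells with 500 µM auxin for 4 h and 3 without, all after a label of 10 min. INTS1-AID and parental libraries were not analysed here. Each library held between 5137155 and 6066384 reads assigned to 14538 listed genes. Levels below are normalized read counts as mean ± SD over 3 libraries, and fold changes are auxin plus over auxin minus on the log2(value + 1) scale with the standard error (SE). The normalization sets the median gene to no change, so a change common to all genes would not appear.

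The comparison asks how transcription shifts within hours of losing INTS8, in a study whose title ties loss of Integrator to the integrated stress response. INTS8 itself stood at 844 ± 124 without and 1002 ± 102 with auxin (log2 0.25, SE 0.11, adjusted p = 0.17). The degron acts on the protein, so this RNA level does not check the depletion, and the interval of INTS8 overlaps that of CCNE2 on the opposite strand. Of 12726 genes tested with limma, 1030 were higher and 450 were lower with auxin at an adjusted p under 0.05. Of these, 299 were at least 2-fold higher and 15 at least 2-fold lower. In 1019 of the higher and 442 of the lower genes all 3 libraries of each group lay apart. Over all tested genes, 31.3% had groups that did not overlap, where chance gives 10%. The split of calls moved with the libraries used. Auxin minus replicate 1 and auxin plus replicate 3 differed most from their own replicates, with a chi-square of 6.83 and 6.46 per gene for the former against 1.35 between the other auxin minus libraries, and 5.53 and 4.16 for the latter against 1.94. Without both, 1762 genes were higher and 1699 lower. Leaving out single libraries gave 547 higher and 152 lower genes without auxin plus replicate 2, and 233, 180 and 251 lower genes without auxin minus replicate 2, auxin minus replicate 3 and auxin plus replicate 1.

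The gene with the smallest p was TEX14 (ENSG00000121101), which encodes a protein of intercellular bridges in germ cells. It went from 47.2 ± 11.6 to 1286 ± 96.2, a 27.2-fold rise (log2 4.76, SE 0.15, adjusted p = 5.6e-10). CRISPLD2, a secreted protein gene, went from 4.80 ± 0.79 to 120 ± 13.2 (log2 4.38, SE 0.24). PCDH19, a protocadherin gene, rose 13.9-fold from 27.8 ± 4.61 to 396 ± 12.1. Among called genes with a mean of at least 50 and groups apart, the others with the highest folds were FOSB (log2 4.17), FOS (3.76), NEDD9 (3.64), SP6 (3.43), SNAI1 (3.41), SHISA2 (3.41) and CDKN2B (3.20), of which SNAI1 encodes a repressor of epithelial genes and CDKN2B an inhibitor of cell-cycle kinases. CDKN2B overlaps a listed gene on the opposite strand, as do TEX14, TMEM80 and, below, INTS6L, DDIT3, RPS28 and CCNE2. Whether counting used the strand is not given in the sources used here, so part of their reads may belong to the other gene. Falls were smaller. ZC3H6 went from 111 ± 26.9 to 49.5 ± 14.1 (log2 -1.15, SE 0.22, adjusted p = 0.0045), and DOK6 from 73.3 ± 10.6 to 33.9 ± 3.12 (log2 -1.09). LINGO2 (log2 -1.04), SEMA3E (-1.03), GPM6A (-1.01), TMEM80 (-0.97), FOXP2 (-0.95), PRKACB (-0.94), STK39 (-0.92) and the histone gene H2AC15 (-0.92) followed. LINGO2, SEMA3E, GPM6A and FOXP2 are known for roles in neurons and axon guidance, though the fixed neuronal list, below, had 3 of 6 genes higher. The intervals of LINGO2, FOXP2, DOK6, GPM6A, STK39 and SEMA3E cover 1275980, 607439, 448200, 369758, 293574 and 285902 bases. Those of PRKACB, ZC3H6, TMEM80 and H2AC15 cover 160437, 64467, 8539 and 496.

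**Figure D1:**
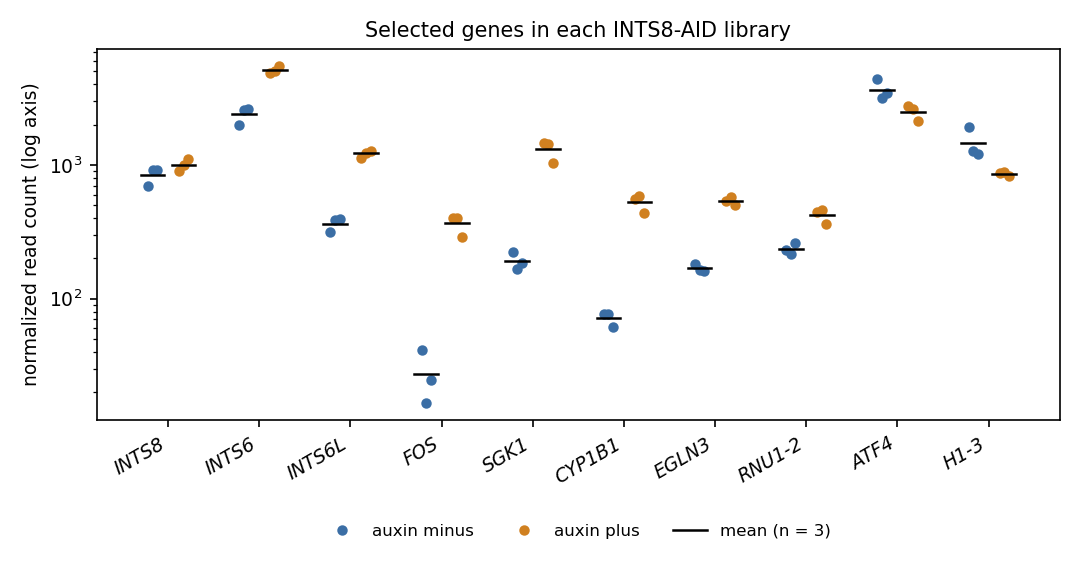
Normalized read count on a log axis for 10 genes in each of the 6 INTS8-AID libraries, with blue points for auxin minus, orange points for auxin plus and a black bar at the mean of 3. INTS6L, FOS, SGK1, CYP1B1 and EGLN3 lie higher in all auxin plus libraries, ATF4 and H1-3 lie lower, and the INTS8 values of the groups overlap.

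Among Integrator subunits, 6 of 20 tested genes rose and none fell, or 7 adjusted over the list alone, and 4 or 5 rose when 1 library was left out. INTS6L, a paralog of the phosphatase-module subunit INTS6, rose 3.35-fold from 364 ± 44.5 to 1216 ± 74.2 (log2 1.74, SE 0.10, adjusted p = 1.6e-07). INTS6 itself rose 2.17-fold from 2379 ± 353 to 5127 ± 308. NABP1, which encodes a single-strand DNA-binding protein found with Integrator, rose 2.25-fold (log2 1.17, SE 0.13). INTS2 (log2 0.66), C7orf26 (0.54), whose product is an Integrator subunit, and INTS14 (0.32) rose less. The other 14 genes did not pass, among them INTS1 (log2 -0.20, adjusted p = 0.49) and INTS11, the endonuclease (log2 -0.59, adjusted p = 0.16). The list as a whole lay higher by camera (median log2 0.089, adjusted p = 0.0064), with adjusted p = 0.25 with an estimated correlation and fry adjusted p = 0.0035. Its median lay within the central 95% of random lists matched on mean level (-0.13 to 0.098). Of 12 genes of protein phosphatase 2A and its partners none passed (median log2 -0.05, camera adjusted p = 0.58), and 12 RNA polymerase II subunit genes held 1 that passed, POLR2A, the largest subunit (log2 0.67, SE 0.11, adjusted p = 0.0012; list adjusted p = 0.86).

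Immediate early genes respond within minutes to growth factors and stress. Their list had the highest median and the smallest camera p at the preset correlation, though not the smallest p by fry. Of 49 tested, 36 rose and none fell, and adjusted over the list alone 38 rose and 1 fell. The median log2 fold change was 0.91 (camera adjusted p = 1.1e-25, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.013). FOSB went from 7.28 ± 2.43 to 145 ± 24.6 and FOS, which like FOSB encodes a Fos-family part of the AP-1 transcription factor, from 27.5 ± 12.7 to 365 ± 66.1 (log2 3.76, SE 0.26, adjusted p = 6.7e-07). SGK1, a serum- and glucocorticoid-induced kinase gene, rose 6.79-fold from 191 ± 28.6 to 1312 ± 245, PLK2 4.94-fold, and the orphan nuclear receptor gene NR4A3 3.78-fold. DUSP5 and DUSP6, which encode phosphatases that restrain MAP kinases, rose by a log2 of 2.39 and 1.69. Also higher were the growth-factor feedback gene SPRY4 (log2 3.96), ARC (2.83), GADD45B (2.04) and KLF4 (1.87). EGR1 rose 2.22-fold (log2 1.15, SE 0.25, adjusted p = 0.0098). JUN was near the threshold, at 710 ± 346 and 1133 ± 187 (log2 0.76, SE 0.23, adjusted p = 0.049), and its groups overlapped. JUN stood at 1107 in auxin minus replicate 1 against 541 and 481 in the other auxin minus libraries. It passed without that library, but not in 4 of the 6 fits that left out 1 library, with adjusted p = 0.15 and 0.18 without auxin minus replicates 2 and 3 and 0.14 and 0.16 without auxin plus replicates 1 and 2, and not with TMM or library-total scaling, edgeR without a block, DESeq2 or limma-voom. MYC (log2 0.04) and KLF6 (-0.26) did not pass. The mean of the list in auxin minus replicate 1, relative to each gene's mean over all libraries, was -0.27, against -0.76 and -0.73 in the other auxin minus libraries, and in auxin plus replicate 3 it was 0.38 against 0.73 and 0.65.

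Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, did not move as a group. Of 43 tested, 6 rose and 2 fell, or 6 and 4 adjusted over the list alone. The median log2 fold change was -0.05 while the mean was 0.08, and camera took the direction as up (adjusted p = 0.85, fry adjusted p = 0.77). ATF3 rose 2.90-fold from 160 ± 77.4 to 438 ± 66.8 (log2 1.54, SE 0.23, adjusted p = 7.3e-04). DDIT3, which encodes CHOP, rose 2.24-fold from 248 ± 41.7 to 559 ± 115. CTH, a gene of cysteine synthesis, rose 1.98-fold, and ALDH1L2 (log2 1.10), VEGFA (0.72) and ULBP1 (0.67) also rose. ATF4 fell from 3642 ± 631 to 2486 ± 334 (log2 -0.55, SE 0.13, adjusted p = 0.014), and 0.058 was its adjusted p without auxin plus replicate 2. SHMT2 was the other gene that fell (log2 -0.40). The amino acid gene ASNS (log2 0.17, adjusted p = 0.30), TRIB3 (-0.23, 0.37) and CHAC1 (-0.36, 0.62) did not pass. Without the libraries that stood apart, 12 targets rose, 4 fell and the list passed at the preset correlation (median log2 0.07, adjusted p = 0.0048). Without auxin minus replicate 1 alone it did not pass (median log2 0.02, camera adjusted p = 0.063). With the replicate number as a block, edgeR called 12 targets higher and 7 lower. The estimated correlation was used only with all libraries, where it gave this list an adjusted p of 0.94. Among 15 genes of eIF2 kinases and phosphatases, OMA1 (log2 0.59), a mitochondrial stress protease, and EIF2AK3 (0.34), the endoplasmic reticulum kinase, rose. EIF2AK2, which encodes the double-stranded RNA sensor PKR, stood at 933 ± 75.6 and 863 ± 24.5 (log2 -0.11, adjusted p = 0.46), and the list had an adjusted p of 0.91. Of 20 interferon-stimulated and double-stranded RNA sensor genes, IRF1 rose by a log2 of 1.13, while DDX58 (log2 0.08) and IFIH1 (0.05), both RNA sensors, did not pass, nor did the list by camera (adjusted p = 0.16), though it did by fry (0.028). Of 29 genes of the unfolded protein response DNAJC3 passed with all libraries (log2 0.37), and not adjusted over the list alone, with an adjusted p of 0.32 for the list. Without auxin minus replicate 1, 5 of these genes rose, and without both libraries that stood apart 5 rose, 1 fell and the list passed at the preset correlation (adjusted p = 0.049, against 0.43 with an estimated correlation and all libraries). EIF2AK3 and DNAJC3 each lost their call in 4 of the fits that left out 1 library.

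Lists of other response programs were shifted up by camera at the preset correlation. Of 10 tested targets of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, 5 rose and none fell, the same adjusted over the list alone (median log2 0.57, camera adjusted p = 7.6e-06, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.0035). CYP1B1, a xenobiotic-metabolizing oxidase gene, rose from 71.9 ± 9.25 to 525 ± 76.5 (log2 2.85, SE 0.14), and CYP1A1 rose 6.10-fold from 12.6 ± 1.75 to 82.0 ± 11.2. TIPARP, an AHR feedback repressor gene, rose 2.07-fold, and HES1 (log2 0.84) and ALDH3A1 (1.88) also rose. Of 18 targets of the hypoxia-inducible factors, 10 rose and none fell, or 11 adjusted over the list alone (median log2 0.38, camera adjusted p = 7.6e-06, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.0035). The prolyl hydroxylase gene EGLN3 rose 3.19-fold from 169 ± 11.2 to 541 ± 36.9, ADM 2.20-fold, NDRG1 1.67-fold and PFKFB3 1.51-fold. Of 24 p53 targets 6 rose and 1, SPATA18, fell, the same adjusted over the list alone (median log2 0.14, camera adjusted p = 0.025, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.013). CDKN1A, the cell-cycle inhibitor p21, rose 2.28-fold from 77.8 ± 13.5 to 179 ± 35.4, BTG2 2.69-fold, PLK3 2.37-fold and the DNA polymerase gene POLH 1.77-fold, and BTG2 and PLK3 were also on the immediate early list.

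**Figure D2:**
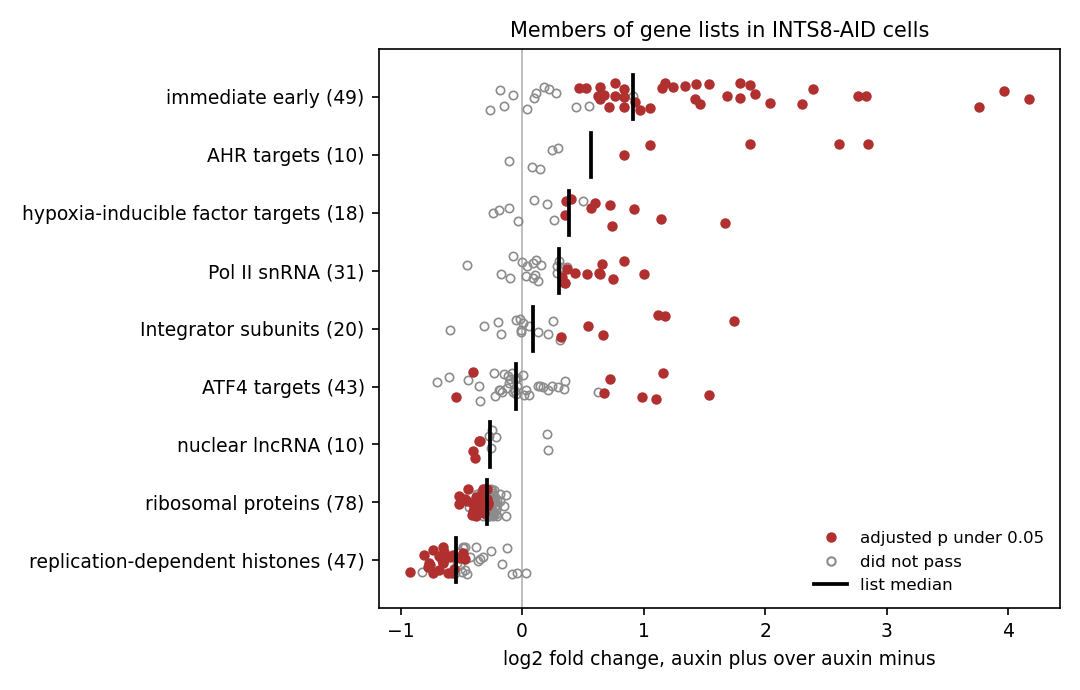
Log2 fold change, auxin plus over auxin minus, of each tested member of 9 gene lists, with the number tested in brackets. Filled red points passed at an adjusted p under 0.05, open grey points did not, and black bars mark list medians, which run from 0.91 for immediate early genes to -0.55 for replication-dependent histone genes.

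Small nuclear RNAs (snRNAs) made by RNA polymerase II are cut at their 3' ends by Integrator. Of 31 tested genes of this list, 12 rose and none fell, or 13 adjusted over the list alone (median log2 0.30, camera adjusted p = 2.2e-05, adjusted p = 0.42 with an estimated correlation). The list did not pass by fry (adjusted p = 0.092). The count fell to 6 without auxin plus replicate 2 and to 7 without auxin minus replicate 2, auxin minus replicate 3 or auxin plus replicate 1. RNU1-2, a U1 gene, went from 236 ± 23.4 to 423 ± 56.6 (log2 0.84, SE 0.12, adjusted p = 4.3e-04). RNU1-1 rose 1.68-fold, RNU5B-1 1.57-fold and RNU5A-1 1.56-fold, and RNU4-1 (log2 0.63) and RNU2-2P (0.53) also rose. U1, U2, U4 and U5 genes have near-identical copies, so reads may be split among them and the values of single copies are uncertain. The RNA polymerase III list held 5 tested genes and none passed, while 1 fell adjusted over the list alone (median log2 -0.18, adjusted p = 0.32). TEX14 holds snRNA genes in its interval. In hg38 it spans chromosome 17 from 58556678 to 58692055 on the minus strand. RNU1-85P (58679527 to 58679690) and RNU1-52P (58677574 to 58677737), U1-like genes on the same strand, lie inside it. RNU1-85P, named after its value was seen, stood at 1144 ± 112 and 1091 ± 124 (log2 -0.07, adjusted p = 0.71). RNU1-52P, too low to be tested, had 0.64 ± 0.56 and 10.8 ± 5.56. RAD51C, which starts next to TEX14 on the plus strand, stood at 216 ± 13.7 and 221 ± 7.14 (log2 0.03, adjusted p = 0.89), and SEPTIN4, farther along on the minus strand, at 6.52 ± 4.26 and 15.8 ± 1.83 (log2 1.31, adjusted p = 0.061).

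**Figure D3:**
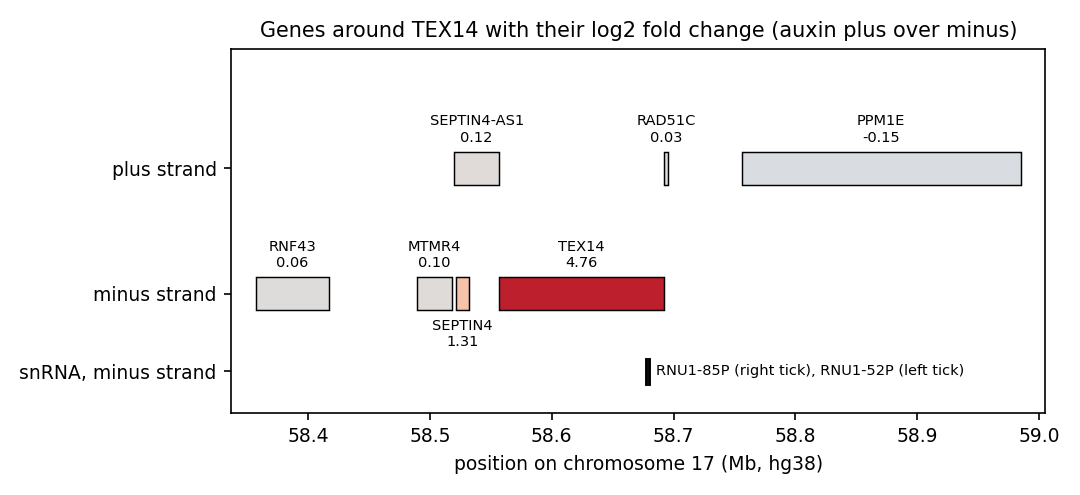
Intervals of the listed genes within 200 kb of TEX14 along chromosome 17 (position in Mb, hg38), by strand, with the log2 fold change of each tested gene under its name and U1-like genes as ticks. TEX14 stands at 4.76, SEPTIN4 at 1.31, and the other named genes between -0.15 and 0.12.

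Replication-dependent histone genes, whose transcripts end in a stem-loop in place of a poly(A) tail, were lower. Of 47 tested, 25 fell and none rose, and 35 fell adjusted over the list alone (median log2 -0.55, camera adjusted p = 3.6e-16, adjusted p = 0.34 with an estimated correlation). The list did not pass by fry (adjusted p = 0.14), and the count that fell was 14 without auxin plus replicate 2 and 16 without auxin plus replicate 3. H1-3 went from 1462 ± 391 to 858 ± 30.3 (log2 -0.74, SE 0.14, adjusted p = 0.0037), H2BC11 from 1297 ± 266 to 741 ± 141 and H2AC11 from 1580 ± 351 to 939 ± 110. Histone copies are near-identical in their coding parts, so single genes are uncertain. The size moved with the libraries that stood apart. Relative to each gene's mean, auxin minus replicate 1 lay at 0.67 against 0.07 and 0.05 in its replicates, and auxin plus replicate 3 at -0.47 against -0.16 and -0.15. The median was -0.34 without the former and -0.25 without both, where 22 genes fell and 3 rose. Of 78 tested ribosomal protein genes, 27 fell and none rose, and 70 fell adjusted over the list alone (median log2 -0.29, camera adjusted p = 1.5e-21, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.050). RPL10 went from 1154 ± 108 to 810 ± 124, RPL13A from 1796 ± 154 to 1314 ± 153 and RPS28 from 584 ± 27.9 to 441 ± 8.72. Without both libraries that stood apart the median was -0.18 and 42 fell, while 6 fell without auxin plus replicate 2 and 8 without auxin plus replicate 3 or auxin minus replicate 3.

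Of 10 nuclear long noncoding RNAs (lncRNAs), 4 fell and none rose, and adjusted over the list alone 8 fell and 2 rose (median log2 -0.27, camera adjusted p = 0.0046, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.0035). All 4 host small nucleolar RNAs in their introns. SNHG1 went from 6773 ± 618 to 5118 ± 338, GAS5 from 5469 ± 117 to 4186 ± 58.6, SNHG3 from 4208 ± 121 to 3315 ± 72.9 and SNHG15 from 1623 ± 192 to 1265 ± 130, with adjusted p from 0.0099 to 0.042. Each of these calls ended without at least 1 library, for GAS5 with an adjusted p of 0.054 without auxin minus replicate 3 and 0.065 without auxin plus replicate 2. MALAT1 (log2 0.22, adjusted p = 0.15) did not pass. Of 16 housekeeping genes, EEF1A1 fell by 0.37 and PPIA fell by 0.26 on the log2 scale, and adjusted over the list alone 5 fell and 1 rose (list median -0.13, camera adjusted p = 0.025, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.11). The list's call ended without auxin minus replicate 1 (adjusted p = 0.070) and without auxin plus replicate 3 (0.093). EEF1A1 lost its call in 4 and PPIA in 5 of the 6 fits that left out 1 library.

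Cell-cycle lists did not pass camera. Of 30 S-phase genes, RRM2, CCNE2, CCNE1 and GINS4 rose, with log2 0.54, 0.75, 0.57 and 0.45, and CDT1 fell (-0.54). Adjusted over the list alone 4 rose and 3 fell (list adjusted p = 0.32, fry adjusted p = 0.092). The median log2 of these genes was -0.13, at percentile 0.24 of random lists matched on mean level. Without both libraries that stood apart 4 rose and 7 fell, and edgeR with the replicate number as a block called 4 higher and 9 lower. Of 25 mitotic genes, NEK2, CENPE, HMMR and KIF20A rose and BIRC5 fell, or 5 and 1 adjusted over the list alone. This list passed by fry (adjusted p = 0.018) and not by camera (0.13). Among 29 pausing and elongation factor genes, HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose 2.83-fold from 566 ± 86.9 to 1600 ± 221, and ELL2 (log2 0.87) and CTR9 (0.45) rose (list adjusted p = 0.85). Cholesterol synthesis genes held 3 of 24 that rose, IDI1, SC5D and INSIG1 (adjusted p = 0.32), and without both libraries that stood apart 6 rose and the list passed at the preset correlation (0.014, against 0.75 with an estimated correlation and all libraries). Of 8 NF-kB targets TRAF1 (log2 2.12) and NFKBIZ (1.99-fold) rose, or 3 adjusted over the list alone (camera adjusted p = 0.15, fry 0.019, and camera 0.040 at the preset correlation without both libraries that stood apart, against 0.30 with an estimated correlation and all libraries). CPSF7 (log2 -0.34) was the gene that fell among 23 cleavage and polyadenylation genes (camera adjusted p = 0.15, fry 0.018). With the replicate number as a block, edgeR called 9 of them lower and 1 higher. None passed among 23 exosome and RNA turnover genes (camera adjusted p = 0.17, fry 0.050), 14 NRF2 targets (0.65) and 12 heat shock genes (0.58). In fits that left out 1 library, calls ended 5 times for BIRC5, 4 times for CPSF7 and INSIG1, 2 times for GINS4 and NEFM and 1 time for CCNE1. As markers of other cells, neuronal genes held 3 of 6 that rose, TUBB3 (log2 2.30, 12.4 ± 3.07 to 65.6 ± 18.6), NEFM (0.97) and ELAVL2 (0.77), and adjusted over the list alone 1 also fell, with camera adjusted p = 0.021, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.027 and camera adjusted p = 0.38 over genes with a mean of at least 50. No blood, HeLa or mitochondrially encoded marker could be tested. Of these lists 3, 0 and 0 genes were listed.

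By class, lncRNAs had a higher median than protein-coding genes, a difference that was not tested. Of 755 lncRNAs tested, 80 rose and 8 fell (10.6% and 1.06%), with a median log2 of 0.21 that ranged from 0.067 to 0.27 over the 9 pairs of an auxin plus and an auxin minus library. Of 11733 protein-coding genes other than these histones, 923 rose and 413 fell (7.87% and 3.52%, median -0.02). Among 135 pseudogenes 15 rose and 2 fell, and among 56 snRNA genes of all kinds 12 rose and 2 fell. By genomic span, over all tested genes and libraries, genes over 200 kb were the bin with more falls than rises, 80 against 38 of 774. Their median log2 was -0.10. At a mean of at least 50, the bin under 2 kb, which includes the histone genes, also had more falls, 32 against 19 of 265. At that level 25 of 42 replication-dependent histone genes fell and none rose. Among the 207 protein-coding genes under 2 kb at any tested level, histones left out, 8 rose and 6 fell. Between 10 and 50 kb, 438 rose and 130 fell of 5442 (median -0.01). Across genes, which are not independent replicates, the fold change had a Spearman's rho of -0.01 with span. That value depended on the libraries. Over library pairs it ran from -0.33 to 0.39, and the median of genes over 200 kb from -0.27 to 0.20. Without both libraries that stood apart rho was -0.31. The median log2 then went from 0.12 under 2 kb to -0.22 over 200 kb, where 309 genes fell and 41 rose of 774. Between 50 and 200 kb, 740 then fell and 326 rose.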

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

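Leaving out both libraries that stood apart, limma after TMM scaling, edgeR on recovered reads (the tool fixed beforehand for raw counts) with TMM, library totals or a block, the authors' deposited calls and, for span, all settings but the mean of at least 50 and exonic length were chosen after seeing the data. The counts of 1030 higher and 450 lower genes stayed within 1.5 times under several settings, with 812 to 1049 higher and 390 to 472 lower. These were TMM, library totals, edgeR without a block, DESeq2 and limma-voom. No filter, a mean of at least 50, pseudocounts of 0.1 and 5 and the authors' deposited table were the others. At an adjusted p under 0.01 the counts were 537 and 112, and with a fold of at least 2 they were 299 and 15, as stricter thresholds must lower them. Leaving out 1 library gave 547 to 1159 higher and 152 to 603 lower genes, and the share of calls that were higher was lowest, 65.8%, without auxin minus replicate 1. Without both libraries that stood apart 1762 were higher and 1699 lower, with 1000 and 414 of the calls kept, and 50.9% of calls were higher. The cause was not tested for these. With an estimated correlation 0 of 27 lists passed camera, against 11. Integrator subunits (-0.015) and p53 targets (-0.020) were estimated below the preset 0.01 and still lost their call. Correlation alone thus does not explain the loss. Spearman's rho of fold with span, -0.01 with all libraries, went from -0.18 to 0.078 when 1 library was left out, and to -0.31 without both that stood apart. No named gene changed sign past the threshold under any alternative. Spike-in scaling was not run, as the table lists no fly genes. Depth limits genes of low level most, and the median of all genes stayed between -0.03 and -0.007 under all alternatives.

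With the replicate number as a block (replicate block), limma called 1769 genes higher and 1440 lower, including all 1030 and 450, and edgeR called 1796 and 1556. The labels share numbers but do not say they mark a shared culture or day. Deviations of same-numbered libraries correlated at 0.60, -0.13 and 0.45 across genes, and auxin minus replicate 2 correlated best with auxin plus replicate 3 (0.47), so not every library correlated best with its own number.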

Other observations

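The tests on TEX14, the test that leaves out 2 libraries, the weighing of auxin acting on the receptor and the reading of other splits were chosen after the results were seen. Gene families were formed from all symbol stems with at least 10 tested members, 142 in all, and tested for a surplus of called genes (Fisher's exact test, one-sided, Benjamini-Hochberg over 142). The RPL stem passed for falls, with 22 of 55 members lower and 1 higher (adjusted p = 4.4e-16). The exception was RPL3L, a muscle paralog of RPL3, at log2 2.99 (SE 0.58, adjusted p = 0.0046). The RPS stem, with 6 of 43 lower, did not pass by count (adjusted p = 0.18) but did by camera at the preset correlation (median log2 -0.25, adjusted p = 2.1e-06). Fisher's test takes genes as independent, while the fixed list of ribosomal proteins had an estimated correlation of 0.69. The RPL and RPS stems overlap that list, so they are not separate support for its fall. That list did not pass camera with its estimated correlation (adjusted p = 0.30), which was not computed for the stems. No stem passed for rises. The nearest were the RNU snRNA genes, with 10 of 38 higher, and DUSP, the dual-specificity phosphatases, with 6 of 16 higher, both at adjusted p = 0.078. The SNHG stem of small nucleolar RNA hosts had 4 of 13 lower (adjusted p = 0.061).

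The 2 libraries that stood apart differed from their replicates along gene span. Across 10268 genes with a mean of at least 50, rho with span was -0.63 for auxin minus replicate 1 over the other auxin minus libraries and 0.59 for auxin plus replicate 3 over the other auxin plus libraries, and these contrasts correlated at r = -0.63 across genes. Opposite slopes in a minus and a plus library offset a fall of fold with span, as rho was -0.01 with all libraries and -0.31 without these 2, and which of these is nearer the effect of auxin was not tested.

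Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 1030 genes higher and 450 lower, and the highest of the other splits called 0 in either direction. It shifted 11 lists, and the highest other split 8. In each case 1 of the 10 splits, the real one, gave a result as large. Every other split mixes auxin plus and minus libraries in both groups. The auxin difference then adds to the spread within groups and lowers their calls, so their counts do not measure chance.

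Histone genes fell by a median log2 of -0.55. Without the 2 libraries that stood apart the median was -0.25 (bootstrap interval over genes -0.30 to -0.18). Part of the size thus rests on them. These genes moved together (estimated correlation 0.87 with all libraries), so the interval measures spread among genes, not between libraries. Relative to each gene's mean, the auxin minus libraries left lay at 0.07 and 0.05 and the auxin plus libraries at -0.16 and -0.15. That argues against the 2 libraries as the only source of the fall, though few libraries are left. A fall of short single-exon transcripts in general is argued against, as 94 other short single-exon protein-coding genes had a median of -0.017 (-0.089 to 0.077). These genes were not matched to histone genes in length, so an effect at histone length was not tested. The 207 protein-coding genes with a span under 2 kb, histones left out, had a median log2 of -0.13, with 8 higher and 6 lower. A lower output of histone genes after loss of INTS8, or a change in the share of cells in S phase, stays open. The share of cells in S phase was not measured. The list of 30 S-phase genes had a median log2 of -0.13, at percentile 0.24 of random lists matched on mean level. It did not pass camera (adjusted p = 0.32), and 4 of its genes rose and 1 fell, so these values do not decide the question.

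AHR targets rose by a median log2 of 0.57. A rise of any genes at this level is argued against, as the median lay at percentile 100 of 10000 random lists matched on mean level, whose central 95% ran from -0.17 to 0.22. Auxin is an indole compound and may act on the receptor with no loss of INTS8. Such an effect predicts the median above 0 that was seen (0.566328), and it cannot be told apart from loss of INTS8 here, since all auxin plus libraries share both and parental libraries were not analysed here.

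A rise of the whole region around TEX14 is argued against, as 7 other tested genes within 200 kb had a median log2 of 0.056 (-0.070 to 0.12) and none passed, though SEPTIN4, past TEX14 on the same strand, stood at log2 1.31 (adjusted p = 0.061). A candidate explanation is polymerases that run past the end of the U1-like gene RNU1-85P, which sits inside TEX14 on the same strand. They would add reads to TEX14 exons downstream of it. RNU1-52P, farther along the same strand, also had more reads with auxin but was too low to be tested. It too lies inside TEX14, so a rise from the promoter of TEX14 itself could add reads there as well. Among 31 snRNA genes with a mean of at least 50, other genes that hold one on its strand or lie within 20 kb past it numbered 1, STX5 (log2 -0.19, adjusted p = 0.43). On the other strand 6 such genes had a median of -0.086. Of these 1 passed, the low gene AP001160.1 past RNU2-2P (mean 22.6, log2 1.74, adjusted p = 0.0022). Whether counting used the strand is not given. A single other gene on the strand of an snRNA gene is too few, so this explanation and a rise from the promoter of TEX14 itself cannot be told apart.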
